A study of Mus musculus with 4 samples.

How the data were processed

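Binding of the histone lysine demethylase KDM4B was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse adipocytes. The labels' protocols state that preadipocytes came from Kdm4b knockout mice, received either a control retrovirus or one encoding Flag-tagged KDM4B, and were kept in adipogenic medium for 7 to 10 days. Nuclei were sonicated, complexes were precipitated with the anti-Flag antibody M2, and libraries were made with the KAPA Hyper Prep kit, per the labels' protocols. The series has 4 samples: 1 anti-Flag ChIP and 1 input per virus. Peak lists of the 2 ChIP samples were used; values of the 2 input libraries were not analysed here. There is 1 ChIP library per condition, so differences between conditions have no replicate check and no p-value is given.

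Reads were aligned to mm9 with Bowtie, per the submitters' processing notes. The version, the peak caller, its threshold and the use made of the inputs are not given in the sources used here. Each list holds a chromosome, a start, an end, a running name and a whole number per peak. That number is treated as a score: the authors deposited it without a stated definition or normalization. Within each list it rose with width (Spearman rho 0.95 across the Flag-KDM4B peaks and 0.87 across the control peaks), as a sum over bins would, but it was not taken as a read count. Scores were used only to describe, rank and filter peaks within a list and were not compared between lists. Read depth per library is unknown, and the number of peaks in a list depends on it.

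In both lists, starts end in 01 and ends in 00 without exception, so coordinates were read as 1-based and inclusive on a 100 bp grid. No peaks of a list touched; neighbouring peaks were at least 300 bp apart. Peaks reach position 196840500 of chromosome 1. The control list names a chromosome 20, and the Flag-KDM4B list names X and Y; names were kept as deposited. No mm9 sequence or gene annotation was used here, and coordinates were not converted between builds, so peaks are reported by position and were assigned to no gene. Shares of peaks in promoters and gene bodies, gene lists, motifs and the Kdm4b locus, all planned for a matching annotation, were therefore not computed.

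Peaks were compared by overlap of at least 1 bp. Flag-KDM4B peaks that overlapped no control peak are called Flag-KDM4B-specific, in the sense of this overlap only. Overlap was set beside 1000 random placements of the control peaks on the grid within the span of peaks of their chromosome, and 1000 moves of each control peak by 10 kb to 100 kb, which keep regional density. Densities are per Mb of the span from the first to the last peak of a chromosome over both lists, which stands in for chromosome length. Clustering is the share of peaks with a neighbour within 10 kb. Shares carry 95% Wilson intervals and densities 95% exact Poisson intervals, which cover counting error only and treat peaks as independent. Specific peaks were not independent, with a variance over mean of 9.1 per autosomal 1 Mb window, so the density intervals are too narrow. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap code was tested on simulated data: it found 200 of 200 control peaks laid on Flag-KDM4B peaks and called 0 of 1793 peaks laid elsewhere.

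The rule for named peaks, set before the data were examined, took the 10 highest-scoring Flag-KDM4B-specific peaks and the 5 highest-scoring control peaks. Dense runs and 1 Mb windows were chosen after their values were seen. The settings varied, as set beforehand, were peaks at or above the median score of their list, merging of touching peaks, other overlap rules, other clustering distances, counting peaks within 10 kb once, and all Flag-KDM4B peaks in place of the specific ones. Settings added once the lists had been opened were reading chromosome 20 as X, using peaks wider than 100 bp only, joining peaks before counting, drawing subsets of equal size, comparing X with the autosomes at a common score limit, and moving control peaks locally. The local moves were set before the overlap of the lists had been computed.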

Results

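Binding sites of KDM4B were sought across the genome of adipocytes differentiated from Kdm4b knockout preadipocytes, in which the only KDM4B expected is the Flag-tagged protein delivered by retrovirus. Knockout adipocytes with a control retrovirus, precipitated with the same anti-Flag antibody, measure the background of the precipitation. Each condition was represented by 1 ChIP library, and the read depth of both is unknown. Coordinates are mm9 positions.

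The Flag-KDM4B list held 14607 peaks and the control list 2013, a ratio of 7.26. Flag-KDM4B peaks covered 4173 kb and control peaks 421 kb, a ratio of 9.91. Flag-KDM4B peaks were wider, with a median of 200 bp against 100 bp and a mean of 286 bp against 209 bp. Peaks of a single 100 bp bin made up 39.1% of the Flag-KDM4B list (95% Wilson interval 38.3 to 39.9%) and 59.8% of the control list (57.7 to 61.9%). Peaks of 500 bp or more made up 17.8% (17.1 to 18.4%) and 9.39% (8.19 to 10.7%). The widest Flag-KDM4B peak spanned 2700 bp and the widest control peak 2300 bp. The authors' score had a median of 36 in the Flag-KDM4B list (quartiles 18 and 69) and of 15 in the control list (quartiles 12 and 31), on scales not stated to be common. The ratio of peak numbers refers to these 2 libraries and has no error across cultures.

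**Figure D1:**
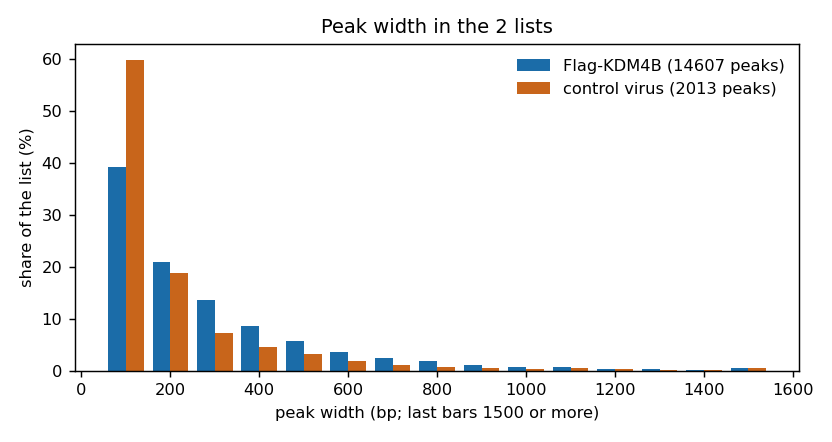
Share of each list (vertical axis, percent) by peak width in bp (horizontal axis, steps of 100 bp, the last bars holding 1500 bp or more), for 14607 Flag-KDM4B peaks and 2013 control-virus peaks. Single-bin peaks made up 39.1% of the first list and 59.8% of the second.

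The comparison with the control virus asked which Flag-KDM4B peaks also appear without Flag-KDM4B. Of the Flag-KDM4B peaks, 645 (4.42%, interval 4.09 to 4.76%) overlapped a control peak and 13962 (95.6%) did not. In the other direction, 669 control peaks (33.2%, 31.2 to 35.3%) overlapped a Flag-KDM4B peak and 1344 did not. Random placement of the control peaks reached a median of 5 overlapped Flag-KDM4B peaks and a highest value of 13 in 1000 draws. Moving each control peak by 10 kb to 100 kb reached a median of 23 and a highest value of 39. The observed 645 lay above both ranges. The share depended on the rule: it was 1.71% when 50% of the Flag-KDM4B peak had to be covered and 11.2% when edges within 1 kb counted.

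Overlap with the control was concentrated in the strongest Flag-KDM4B peaks. When the list was ranked by score and cut into 10 equal classes, in the lowest class 11 of 1461 peaks (0.753%, 0.421 to 1.34%) overlapped a control peak, and in the highest class 303 of 1460 (20.8%, 18.8 to 22.9%). The contrast was weaker when peaks were ranked by score per 100 bp, at 1.16% in the lowest class and 14.2% in the highest. Among the 122 peaks with a score of 300 or more, 72 overlapped (59.0%, 50.1 to 67.3%). Among the 435 peaks of 1000 bp or more, 155 overlapped (35.6%, 31.3 to 40.2%). Shared Flag-KDM4B peaks had a median width of 500 bp and the others 200 bp, and a wider peak meets another peak more easily. In 1000 local moves of the control peaks, at most 6 of the 122 and at most 10 of the 435 were overlapped.

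**Figure D2:**
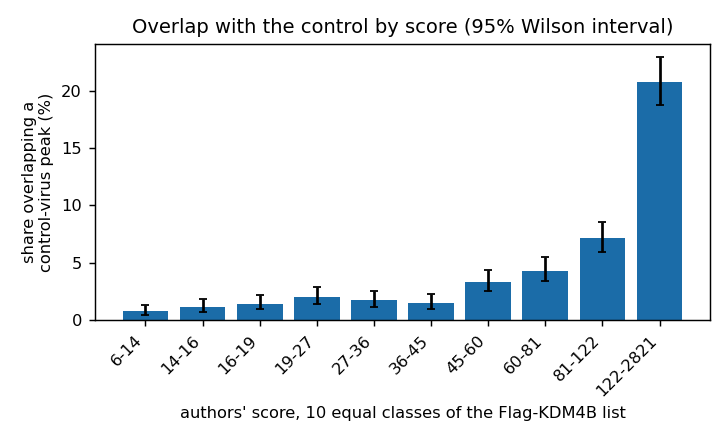
Share of Flag-KDM4B peaks that overlap a control-virus peak (vertical axis, percent) in 10 equal classes of the list by the authors' score (horizontal axis, score range of each class); error bars are 95% Wilson intervals. The share was 0.753% in the lowest class and 20.8% in the highest.

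Control peaks that overlapped no Flag-KDM4B peak mostly lay close to one. Of the 1993 control peaks on chromosomes named in both lists, 654 (32.8%, 30.8 to 34.9%) had a Flag-KDM4B peak less than 1 kb away without overlap, against a median of 1.05% and a highest value of 1.81% in random placements. Of these, 150 directly adjoined a Flag-KDM4B peak, 101 were 100 bp away and 25 were 900 bp away. A further 412 (20.7%) lay at 1 kb to under 10 kb, against a random median of 6.82%. At 100 kb or more lay 53 control peaks (2.66%), against a random median of 63.2%. These placements ran over the whole span of a chromosome and did not keep regional density. Shared regional density would by itself widen these contrasts, and no local moves were set beside the distances.

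**Figure D3:**
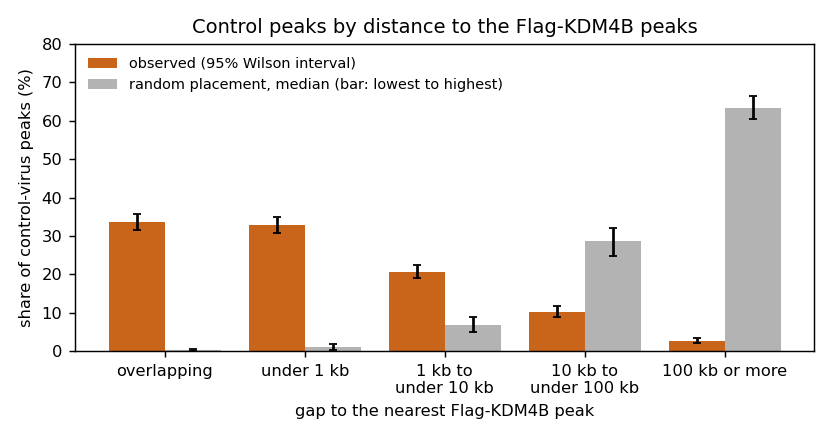
Share of the 1993 control-virus peaks (vertical axis, percent) by the gap to the nearest Flag-KDM4B peak (horizontal axis); orange bars are observed with 95% Wilson intervals, and grey bars are the median of 1000 random placements with their lowest and highest values. Observed shares exceeded placement up to 10 kb and fell below it from 10 kb.

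The highest scores of both lists lay at the same places. The 2 highest control peaks were at chromosome 2, 98506501 to 98507400 (score 2786) and 98502401 to 98503100 (score 2358). The highest Flag-KDM4B peaks were at chromosome 2, 98506501 to 98507400 (score 2821) and 98502501 to 98503000 (score 1869). The next control peaks were on chromosome 9, from 3000001 to 3000700 (score 1050) and from 35112901 to 35113100 (score 726), and the latter met the third Flag-KDM4B peak, from 35112801 to 35113100 (score 1027). The fifth control peak was at chromosome 8, 129116301 to 129117400 (score 591). All 5 overlapped a Flag-KDM4B peak. Of the 10 highest Flag-KDM4B peaks, only that at chromosome 1, 90175401 to 90176800, overlapped no control peak. Per 100 bp that peak scored 43.7, against 313 to 374 for the Flag-KDM4B peaks named before it. In the control list, the peaks on chromosomes 2 and 9 scored 150 to 363 per 100 bp and the fifth 53.7. The named peaks on chromosomes 2 and 9 were listed with the control virus too, so their listing cannot be taken as KDM4B binding. Whether concentrated scores elsewhere mark binding was not tested.

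Among the 13962 Flag-KDM4B-specific peaks, the highest scores fell in a stretch of chromosome 1 that held 3 of the 10 named peaks. These were at 90175401 to 90176800 (score 612), 90116901 to 90117600 (score 550) and 90184101 to 90185000 (score 408), with the nearest control peak 312 kb to 379 kb away. Per 100 bp these peaks scored 43.7, 78.6 and 45.3, against 24.4 to 37.7 for the other named specific peaks. Chromosome 15 held 2, at 52785301 to 52787100 (score 452) and 80084501 to 80086100 (score 398). Chromosome 12 also held 2, at 7925801 to 7927200 (score 416) and 88728701 to 88730200 (score 407). The others were at chromosome 11, 70468401 to 70470000 (score 421), chromosome 13, 97157801 to 97158900 (score 415), and chromosome 2, 72590801 to 72592500 (score 414). For 8 of the 10 the nearest control peak was 225.7 kb or more away. It was 2.2 kb away for the peak on chromosome 11 and 1 kb away for the second peak on chromosome 15.

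Flag-KDM4B-specific peaks were unevenly spread over the chromosomes. The 19 autosomes together had 5.75 per Mb of span. Chromosome 11 had the most, 9.59 per Mb (95% Poisson interval 9.04 to 10.2), which is 1.67 times the autosomal density, and held 8.14% of the specific peaks in 4.64% of the span. Chromosome 19 followed with 8.73 (7.99 to 9.53) and chromosome 7 with 6.64 (6.23 to 7.06). With peaks within 10 kb counted once, chromosome 17 ranked above chromosome 7. Chromosome 14 had the fewest among autosomes, 4.21 (3.85 to 4.60). Chromosome X had 187 peaks, 1.18 per Mb (1.01 to 1.36), which is 0.204 times the autosomal density (0.176 to 0.236). The control list names no X, so none of the 187 could overlap a control peak, and all count as specific by naming. Read as X, chromosome 20 of the control list has 2 peaks that overlap Flag-KDM4B peaks on X. The lowest score of a listed Flag-KDM4B peak was 8 on X and 11 on the autosomes, and among specific peaks at or above the median score the X density was 0.0809 times the autosomal one. Chromosome Y had 6 peaks.

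Control peaks were also densest on chromosome 11, at 1.68 per Mb (1.45 to 1.93), followed by chromosome 17 at 1.61 (1.36 to 1.89) and chromosome 5 at 1.45 (1.26 to 1.66), and among autosomes sparsest on chromosome 1 at 0.471 (0.379 to 0.578). On the chromosome that the control list names 20 they had 0.130 per Mb (0.0795 to 0.201), which is 0.156 times the autosomal control density (0.0956 to 0.242). Across the 19 autosomes the densities of specific and control peaks were correlated, with Pearson's r 0.75 and Spearman's rho 0.73. Without the 2 autosomes farthest from the median specific density, r was 0.74. Chromosomes of 1 pair of libraries are not independent replicates, so no p-value is given. The ratio of Flag-KDM4B to control peaks ranged from 4.36 on chromosome 17 to 10.5 on chromosome 1.

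**Figure D4:**
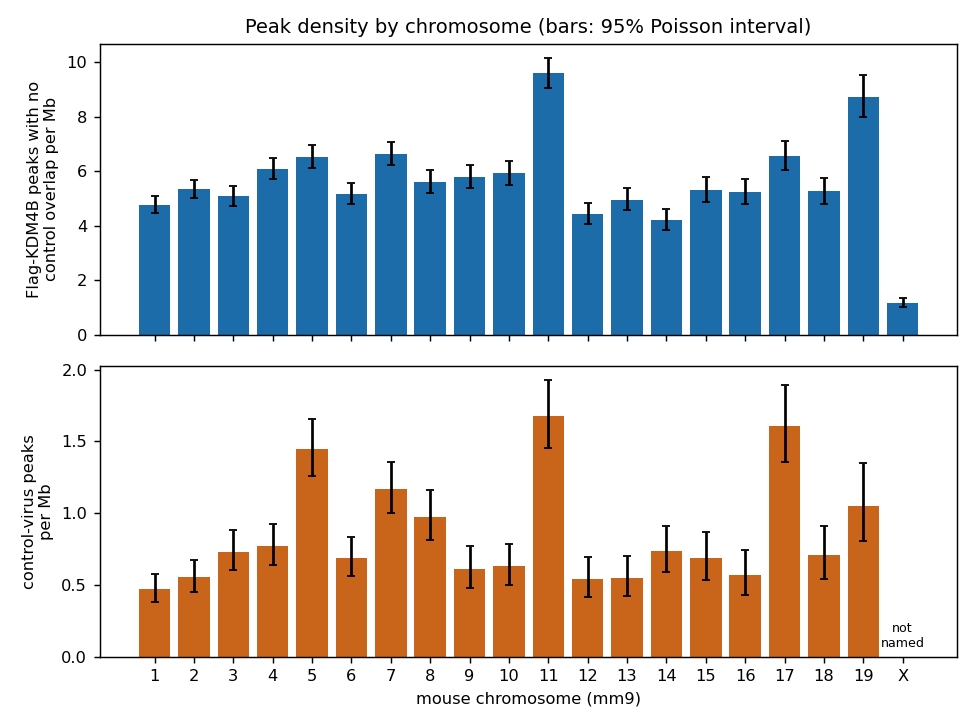
Flag-KDM4B peaks without control overlap (upper panel) and control-virus peaks (lower panel) per Mb of peak span (vertical axes) by mouse chromosome in mm9 (horizontal axis); bars carry 95% Poisson intervals, and the control list names no chromosome X. Chromosome 11 was densest in both panels, at 9.59 and 1.68 per Mb, and X had 1.18 specific peaks per Mb.

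At the scale of 1 Mb, specific peaks gathered in part of the genome. Of 2414 autosomal windows, 711 (29.5%) held no specific peak, where Poisson placement at the mean of 5.70 per window would leave 0.333% empty. The 143 windows with 20 or more peaks were 5.92% of the windows and held 27.0% of the autosomal specific peaks. The fullest window, chromosome 10 from 80000001 to 81000000, held 52 specific and 16 control peaks. It was followed by 2 windows with 51 specific peaks each, on chromosome 11 from 115000001 (2 control peaks) and from 120000001 (12 control peaks). Control peaks followed the same windows: Spearman's rho across windows was 0.61, against at most 0.08 in 1000 shuffles of windows within chromosomes, and windows without specific peaks held 32 control peaks (1.61% of the autosomal ones).

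Peaks of both lists also came in short runs. A neighbour of the same list lay within 10 kb for 58.9% of the specific peaks (58.1 to 59.7%), against a random median of 11.5%, and for 56.0% of the control peaks (53.8 to 58.1%), against 1.94%. Among peaks at or above the median score of their list, the shares were 41.9% and 55.7%, the opposite order. When specific peaks were drawn at random down to the 2013 of the control list, 16.2% had such a neighbour (lowest 12.7% and highest 20.2% of 1000 draws). Drawing single peaks also breaks up runs, which lowers this share. Within 1 kb, 31.1% of specific and 32.4% of control peaks had a neighbour. The smallest gap, 300 bp, occurred 868 times in the Flag-KDM4B list and 114 times in the control list. Whether runs are parts of a broader region listed as separate peaks was not tested, and random placement treats each peak as separate. Joining specific peaks within 10 kb gave 8584 regions. The region with the most peaks was at chromosome 14, 63851301 to 63890500, with 20 specific and 2 control peaks in 39.2 kb. The next were chromosome 17, 88002001 to 88045000, with 16 specific and 15 control peaks, and chromosome 16, 33764701 to 33807000, with 16 specific and 4 control peaks. Among control peaks, the run with the most peaks was at chromosome 7, 80677901 to 80705000, with 16 control and 12 Flag-KDM4B peaks.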

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

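The tests of the score limit on chromosome X and of the naming of chromosome 20, and the comparisons at a common score limit, were chosen after the values they use had been seen; the other tests in this part had their outcomes stated before the values were computed.

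The control list held 20 peaks on a chromosome named 20, a name that the Flag-KDM4B list does not use and that no mouse autosome has. At the same coordinates, 2 of the 20 (20425401 to 20425800 and 148237301 to 148237900) overlapped a Flag-KDM4B peak on X, against at most 1 in 1000 random placements. The Flag-KDM4B list of chromosome 18 was met once, but it ends at 90752200, and the chromosome 20 peaks reach 166446700, 98.6 kb past the last Flag-KDM4B peak on X. Only chromosomes 1 and 2 reach further in the Flag-KDM4B list, to 196840500 and 181599100, and the control list names both. The 2 overlaps, and the reach of the peaks, are consistent with the explanation that chr20 is chrX under another name, and read that way the overlap of control peaks would be 33.3%. Of the 20 peaks, 8 lay between 166429801 and 166446700, where the Flag-KDM4B list has none.

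The Flag-KDM4B list held 6 peaks on chromosome Y, where the control list has none. The control list is smaller (2013 peaks against 14607), so the lack of Y peaks there is not evidence of a difference. The scores of the Y peaks differed. Of the 6, 5 had scores of 6 to 12, and the peak at 2879601 to 2879700 had a score of 157 in 100 bp.

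Chromosome X had 1.18 Flag-KDM4B peaks per Mb, against 6.02 on the autosomes, and if chromosome 20 of the control list is X, the control had a deficit too, at 0.156 times its autosomal density (0.0956 to 0.242), with a lowest listed score of 7 against 9 or 10 on the autosomes, so a deficit may not be particular to Flag-KDM4B. A stricter limit on X in the listed score itself would need a higher lowest score there. It was 8, against 11 on the autosomes, which argues against a limit of that kind only. A limit set relative to the signal of each chromosome cannot be judged from these values. Because the lowest listed scores differ, Flag-KDM4B peaks were also compared at a score per 100 bp of 12 or more, where X had 82 peaks, 0.515 per Mb against 6.01 (0.0857 times), with a median of 14 against 18. A drop to 50% of the signal at otherwise equal sites gave opposite answers: with autosomal scores per 100 bp lowered to 50%, the sparsest autosome would keep 3.29 peaks per Mb at the lowest value seen on X, above the 1.18 there. At 12 or more, however, the autosomes together would keep 0.511 per Mb, near the 0.515 on X. Single autosomes would then keep 0.321 to 0.986 per Mb, 10 of them at or below X. The bound set beforehand at the lowest value on X assumed that X is listed as fully down to it as the autosomes, which is not known, so lower signal, fewer sites recovered in either precipitation and poorer alignment all stay open.

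Control peaks overlapped 645 Flag-KDM4B peaks, 541 of them in the upper 5 of the 10 score classes. Shared use of the same stretches of the genome at 10 kb to 100 kb is argued against as the cause, since the highest of 1000 local moves met 39 Flag-KDM4B peaks. Carry-over of the Flag-KDM4B library into the control could favour strong peaks; a shared autosomal peak had the higher score per 100 bp with a chance of 0.715 (bootstrap interval 0.695 to 0.737), and 2480 unshared peaks lay above the shared median. The 0.715 lies below the 0.9 set for carry-over, and its interval includes the 0.7 set against it; for the score itself, which follows width and had no limit set, the chance was 0.793. Carry-over as the cause cannot be told apart from background precipitation at the same sites. Input libraries could show whether these sites stand out without precipitation, but could not separate carry-over from background of the antibody.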

How the results depend on the processing

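No paired analysis was possible because each condition has 1 ChIP library, and leaving out a replicate was likewise impossible. Restricting each list to peaks at or above its median score left 7355 Flag-KDM4B and 1047 control peaks by construction. It gave 4.83% of Flag-KDM4B and 35.3% of control peaks overlapping, an X density of 0.0809 times the autosomal one (scores on X are lower), and 41.9% of specific against 55.7% of control peaks with a neighbour within 10 kb, which turns the order of the lists (58.9% and 56.0% for all peaks). In the same setting, 57.7% of control peaks lay within 1 kb of a Flag-KDM4B peak, overlapping ones included, and 75.2% within 10 kb. For all peaks these shares were 67.5% and 86.2%. The overlap rule moved the overlap most. Requiring 50% of the Flag-KDM4B peak to be covered gave 1.71% of Flag-KDM4B and 12.2% of control peaks, and accepting edges within 1 kb gave 11.2% and 67.5%. Among peaks wider than 100 bp, chosen after seeing the data, the shares were 3.42% and 38.3%. Counting peaks within 10 kb once gave an X density of 0.257 and a chromosome 11 density of 1.56 times the autosomal one. Clustering changed with the distance by construction: 31.1% of specific and 32.4% of control peaks had a neighbour within 1 kb, and 82.9% and 66.2% within 50 kb. Subsets of equal size, also chosen later, gave 16.2% of specific peaks. The ratio of peak numbers stayed between 6.95 and 7.28 under the 3 alternatives run for it. The limit at the median score nearly keeps that ratio by construction, and no alternative varied depth or the threshold of the peak caller. Merging touching peaks changed neither list because none touched, and reading chromosome 20 as X changed the overlaps to 4.43% and 33.3%. Peak numbers and overlaps are limited by depths that are unknown. The planned promoter, gene list, motif and Kdm4b locus alternatives were not run, since no mm9 annotation was used here.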

Other observations

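The highest-scoring control peaks without overlap were chosen after their values were seen. The strongest lay at chromosome 13, 49060901 to 49063100 (score 426), chromosome 5, 139470001 to 139472200 (score 370), and chromosome 5, 37052001 to 37052600 (score 366). The first pair were each 2200 bp wide, close to the widest control peak, and the nearest Flag-KDM4B peak lay 0.6 kb and 0.8 kb away. The peak at chromosome 8, 124174901 to 124176200 (score 301, 1300 bp wide), had a Flag-KDM4B peak 0.5 kb away. By contrast, the third peak named lay 34.6 kb from a Flag-KDM4B peak. A peak at chromosome 9, 3022101 to 3022400 (score 361 in 300 bp), lay 21.6 kb from one, on the same stretch as the third-highest control peak. No explanation for these neighbouring but separate peaks was tested.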
